A study of Mus musculus with 12 samples.

How the data were processed

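Liver RNA was measured in 12 mice on 12 one-colour microarrays, 1 mouse per array. The mice lacked factor VII-activating protease (FSAP), a circulating serine protease encoded by Habp2, or were wild-type (WT) littermates, and had either bile duct ligation (BDL), which blocks bile flow and leads to biliary fibrosis, or a sham operation. Each of the 4 groups held 3 mice. Per the labels, littermates came from heterozygous crosses after backcrossing to BALB/c up to the F3 generation, the mice were 20 to 30 weeks old, livers were taken 2 weeks after surgery and snap frozen, RNA integrity was at least 7.2, and 100 ng of total RNA was labelled with Cy3. The labels do not say which part of Habp2 was deleted, nor the sex of the mice. Samples are named by genotype, surgery and the replicate number in their titles.

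The deposited scanner files, 1 per array, hold the intensity of each spot on a linear scale. Per the file headers, they were written by Agilent Feature Extraction 10.5.1.1 with protocol GE1_105_Jan09, and the array was an Agilent one-colour mouse design. The intensity used here, the processed signal, was background-subtracted and detrended within the array but not scaled between arrays, per the file headers. The series matrix holds a log2 value per probe that the authors made from the same arrays. Its column medians lay between 5.655 and 5.66, with 5.6645 for replicate 1 of the FSAP-deficient sham group, and each column correlated with its array's scanner values above 0.998. Set against the scanner values, it behaved as quantile-normalized log2 signal with no centring of genes. The method is not given in the sources used here, so this table served only as an alternative.

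Every array had 44397 spots, of which 43020 were not controls and covered 39429 probes. No spot was saturated, and 98 to 193 spots per array with an outlier mark were left out. Between 54.5% and 62.3% of the spots were well above background on an array, and the 75th percentile of the signal ran from 475 to 1202. The median coefficient of variation of repeated spike-in spots was 6.19% to 15.0%. For arrays, the number of mice, 3 per group, limits the precision. Array pairs of 1 group correlated at 0.990 to 0.993 in WT sham livers, 0.977 to 0.982 in WT livers after BDL, 0.975 to 0.990 in FSAP-deficient sham livers and 0.971 to 0.982 in FSAP-deficient livers after BDL. The first principal component held 60.8% of the variance and parted BDL from sham, and the second held 8.92%. On the second, replicate 1 of the FSAP-deficient sham group stood at -70.75 and the other arrays between -37.64 and 26.92.

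Probes were named through their RefSeq accession where the reference table held it. Of 33063 probes with such an accession, 26412 matched, which changed 3093 symbols, and other probes kept the file's name. Of the resulting 31870 symbols, 12046 were identifiers without a gene symbol. Probe positions are those of the files, on mm9. Transcript annotation of that build was not used, so the exon or untranslated region under a probe is not given. One array, replicate 1 of the FSAP-deficient sham group, was extracted with gene names for 9.26% of its probes and took the others from the shared probe identifiers.

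The analysis took log2 of the processed signal minus each array's 75th percentile on that scale. Spots of 1 probe were averaged, and the brightest probe stood for a symbol. Genes well above background on at least 3 of the 12 arrays were tested, which left 19531 genes, 14202 of them with a symbol. Of 234372 values, 79 were left out with outlier marks. One limma model with the 4 group means was fitted to all 12 arrays, so that the groups share 1 estimate of spread, with 8 residual and 2.69 prior degrees of freedom. Moderated tests were two-sided and adjusted by the Benjamini-Hochberg method at a false discovery rate of 0.05. The 6 comparisons were BDL against sham in each genotype, FSAP-deficient against WT in each surgery, the genotype difference averaged over surgeries, and the interaction of genotype and BDL. "Rose", "fell" and "changed" stand for genes or lists past that threshold, and errors beside a log2 change are standard errors of the model. Where a gene was not well above background on any array of the dimmer group, only a bound is given. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

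The 37 gene lists, with 1157 members of which 1138 were on the array, covered collagens, matrix glycoproteins and proteoglycans, matrix-remodelling enzymes, TGF-beta and PDGF signalling, coagulation and fibrinolysis, bile acid synthesis, bile and organic anion transport, cholesterol synthesis, fatty acid oxidation, lipogenesis, cytochrome P450 enzymes, phase II enzymes, urea cycle with amino acid metabolism and gluconeogenesis, the acute phase, cytokines and chemokines, the interferon response, MHC class II, complement, the cell cycle, p53 targets, endoplasmic reticulum (ER) stress, ribosomal proteins, clock genes, male-biased and female-biased liver genes and sex chromosome genes. Others held markers of hepatocytes, cholangiocytes, stellate cells and myofibroblasts, sinusoidal endothelium, macrophages, neutrophils, T and NK cells, B cells, erythroid cells, pancreas, and mesothelium with adipose tissue. Lists overlap in part and many of their genes are expressed by several cell types of the liver. A list was tested with at least 5 tested members, which held for 36 of the 37 (the sex chromosome list is reported as single genes). Camera, with a preset correlation of 0.01 between genes, compared each list with all other genes, and the same test with the correlation estimated from the arrays stands beside it. Fry, which tests each list against no change and so asks another question, was added after seeing the data.

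The groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Habp2; the 10 largest rises and falls among genes with adjusted p under 0.05, non-overlapping groups (adjusted p alone for the average and the interaction), a gene symbol and signal well above background in both groups; per described list, up to 4 members with the largest change among those past the threshold, or else the 2 with the smallest p; and Acta2, Col1a1, Col1a2, Col3a1, Fn1, Timp1, Tgfb1, Pdgfrb, Krt19 and Cyp7a1 in every comparison. The text prints part of the genes so named. Major urinary protein (Mup) genes are near-identical copies whose probes can share signal, so their single values are uncertain.

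The header fields place the arrays on 4 slides. Slide 1 held the 3 WT sham arrays and replicate 1 of WT after BDL, slide 2 held replicates 2 and 3 of WT after BDL and replicate 2 of the FSAP-deficient sham group, slide 3 held replicate 3 of the FSAP-deficient sham group and the 3 FSAP-deficient arrays after BDL, and slide 4 held replicate 1 of the FSAP-deficient sham group alone, scanned on scan day 2. Both genotypes of 1 surgery never shared a slide, so no genotype difference could be taken within a slide. With slide as a block, the BDL effect in WT rests on 1 BDL array against the 3 sham arrays of slide 1, and that in FSAP-deficient livers on the 3 BDL arrays against 1 sham array of slide 3.

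Alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, median scaling, the series matrix values, no filter and a filter on all 12 arrays, the mean of a symbol's probes, slide as a fixed and as a random block, the replicate number as a block, only the groups compared, a trended robust variance, array weights, an estimated correlation in camera, and leaving out each array in turn. Leaving out the 3 arrays with Y-linked signal, and a term for them in the model, were added after seeing the data. The tests were run on simulated gene values, 10 runs over 19531 genes with 200 changed genes each. Noise was independent between genes and slides had no effect. Spot averaging, scaling, the filter and correlation within lists were thus not tested. Far more genes changed after BDL than in these runs, so recovery there can differ. For BDL against sham in WT it recovered 2%, 40.4%, 88% and 97.4% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, for FSAP-deficient against WT after BDL 0.8%, 42%, 86.8% and 98.6%, and for the interaction 0.8%, 8.8%, 64.4% and 93.6%. Every recovered gene had the right sign. On average 4.1, 6.9 and 4.8 unchanged genes were called per run in these comparisons. The tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.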

Results

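Liver expression was compared between mice without FSAP and WT littermates, 2 weeks after BDL or a sham operation, with 3 mice in each of the 4 groups. The series title names the question as whether FSAP limits fibrosis in this model. Each mouse gave 1 array, and 19531 genes were tested. Values are log2 changes with the standard error (SE) of the limma model and 3 arrays per group unless another number is given, and each array was set to its 75th percentile. With the median in its place, the median change of all tested genes moved from -0.03 to -0.19 for BDL in WT, from -0.16 to -0.36 for BDL in FSAP-deficient livers and from -0.03 to -0.13 for the genotype difference after BDL, so changes are relative to the 75th percentile and small ones depend on it. No list that moved and is described below turned direction under median scaling or quantile normalization. Counts of rises and falls in a list are over all genes tested, followed by the count adjusted over the list alone. The value within the slide that held both surgeries, also the value with slide as a block, follows a list's median after BDL. A gene named as having risen or fallen after BDL kept its call when any 1 array was left out and under every other alternative in which it was tested, unless stated.

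Habp2, the targeted gene, was measured by a pair of probes (19:56394519-56394578 and 19:56395251-56395310, mm9). Its brighter probe stood at 5.45 ± 0.07 (SD, n = 3) in WT sham livers and at -5.63 ± 1.89 in FSAP-deficient sham livers, on the log2 scale relative to the array's 75th percentile. After BDL the levels were 5.05 ± 0.09 in WT and -7.04 ± 0.13 in FSAP-deficient livers. That is at least 850.1-fold lower in sham (log2 change -11.08, SE 0.68, adjusted p = 6.476e-05) and at least 1178-fold lower after BDL (-12.08, adjusted p = 2.65e-05). Among the 6 FSAP-deficient arrays, only replicate 1 of the sham group was still well above background at this probe, at -3.45, and with only the sham groups in the model the same change missed the threshold. The second probe was not well above background on any FSAP-deficient array and was at least 32.6-fold lower in sham and at least 39.5-fold lower after BDL. Whether either probe lies in the deleted part is not given in the sources used here. In WT, Habp2 stood at -0.40 after BDL against sham (limma, adjusted p = 0.69). The model shares 1 spread over all groups, including the FSAP-deficient sham arrays with their SD of 1.89. This p-value therefore does not measure the spread among the WT arrays, and a fall of Habp2 in WT is not excluded.

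Sex chromosome genes differed between arrays. The Y-linked genes Ddx3y and Eif2s3y were well above background, and Xist, the RNA that silences 1 X chromosome in females, was not, on 3 of the 12 arrays. These were replicate 1 of the FSAP-deficient sham group and replicates 1 and 2 of the FSAP-deficient BDL group. None of the 6 WT arrays had Y-linked signal (0 of 6), and Xist was well above background on all of them. Ddx3y stood at 1.54 on the sham array and at 1.15 and 1.03 on the BDL arrays. By these genes the 3 arrays read as male and the 6 WT arrays as female, though the labels do not give sex. Comparisons between genotypes therefore also compare groups with unequal Y-linked signal, and those within FSAP-deficient livers compare 1 of 3 sham arrays with 2 of 3 BDL arrays.

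**Figure D1:**
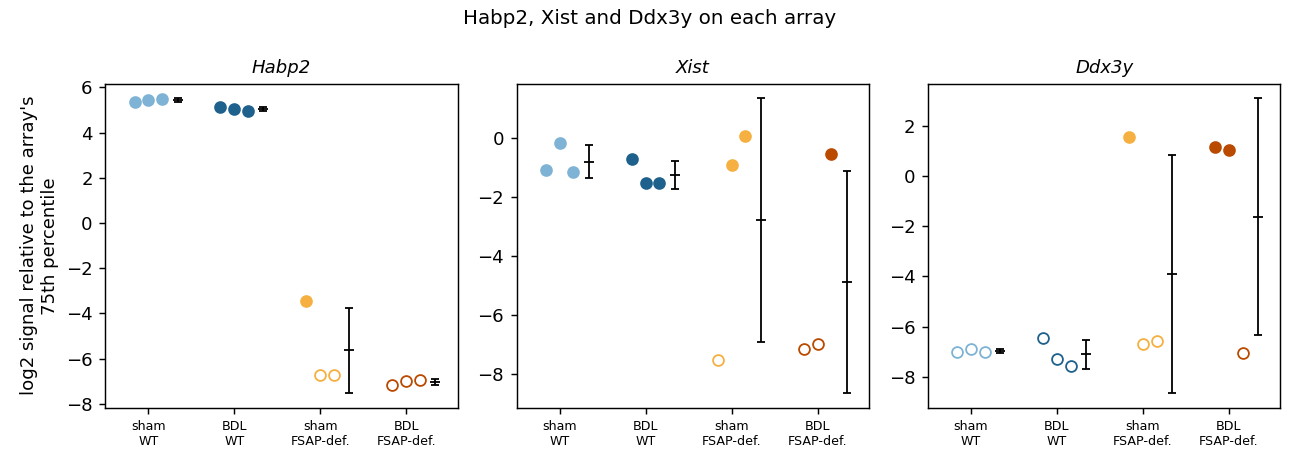
Log2 signal of Habp2, Xist and Ddx3y on each of the 12 arrays, relative to the array's 75th percentile, by group (filled points are well above background, hollow points are not, and the dash and bar give the mean ± SD, n = 3). Habp2 averages 5.45 in WT sham livers and -5.63 in FSAP-deficient sham livers, and Ddx3y is well above background on 3 FSAP-deficient arrays.

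The first comparison asked what 2 weeks of blocked bile flow changed in WT livers. Many matrix, bile duct, macrophage and neutrophil genes rose, and many genes of hepatocyte metabolism fell. Their lists moved with the preset correlation, and 0 of 36 did with an estimated one. Col1a1 (11:94813115-94813174), the main chain of type I collagen, rose 15.4-fold (log2 change 3.94, SE 0.61, adjusted p = 0.0008163), Timp1, an inhibitor of matrix metalloproteinases, rose 84.1-fold, and Krt19, a keratin of bile duct cells, rose 9.86-fold. Car3, a carbonic anhydrase of hepatocytes, fell by 10.33 (SE 1.25). In all, 6415 of 19531 genes changed, 2958 up and 3457 down, of which 1859 rose and 1662 fell at least 2-fold, and 1324 had no gene symbol. The share that rose was 46.1%, and 33.1% under median scaling. The groups did not overlap for 52.1% of genes, where chance gives 10%.

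Of 20 collagens, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.85 and 0.96 within slide 1 (adjusted p = 0.269 with an estimated correlation). Col4a1, a basement membrane collagen, rose 8.82-fold. Col1a2 and Col3a1, fibrillar collagen chains, rose 6.42-fold and 5.79-fold. Within slide 1 they stood at 1.30 and 1.12, and both calls ended there. Acta2, the smooth muscle actin of myofibroblasts, was at 0.72 (SE 0.54, adjusted p = 0.338) and at 0.03 within slide 1. Among 39 matrix glycoproteins and proteoglycans, 16 rose and 1 fell (19 and 2 adjusted over the list alone, median 0.90, within slide 1 0.37, adjusted p = 0.407 with an estimated correlation). They included the basement membrane protein Nid1 (3.88) and Mgp (2.65), an inhibitor of calcification, whereas fibronectin, Fn1, stood at 0.19 (adjusted p = 0.584). Matrix-remodelling enzymes and inhibitors rose in 23 and fell in 2 of 35 (24 and 2 adjusted over the list alone, median 1.65, within slide 1 0.81, adjusted p = 0.258 with an estimated correlation). Timp4, another metalloproteinase inhibitor, was at least 116-fold higher, and the epithelial protease Mmp7 at least 84.1-fold higher. In TGF-beta and PDGF signalling 13 of 36 members rose and 2 fell (15 and 2 adjusted over the list alone, median 0.40, within slide 1 0.31, adjusted p = 0.258 with an estimated correlation), with rises of Tgfb2 (3.54), the activin subunit Inhbb (3.87) and the activin antagonist Fst (3.89). Tgfb1 (0.50, adjusted p = 0.213) and the PDGF receptor Pdgfrb (0.77, adjusted p = 0.0755) did not pass. Pdgfrb passed without replicate 1 of the WT BDL group, at 1.11. Markers of stellate cells and myofibroblasts rose in 11 and fell in 2 of 34 (12 and 2 adjusted over the list alone, median 0.72, adjusted p = 0.578 with an estimated correlation). Their list moved no longer within slide 1 (-0.02) or without replicate 3 of the WT BDL group (0.29). An example is the calcium-binding protein S100a6 (2.92). Mesothelial and adipose markers rose in 7 and fell in 1 of 15 (7 and 2 adjusted over the list alone, median 1.18, and 0.17 with the call ended within slide 1, adjusted p = 0.269 with an estimated correlation), among them Lpl, lipoprotein lipase (4.81), and Msln, mesothelin (2.58).

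**Figure D2:**
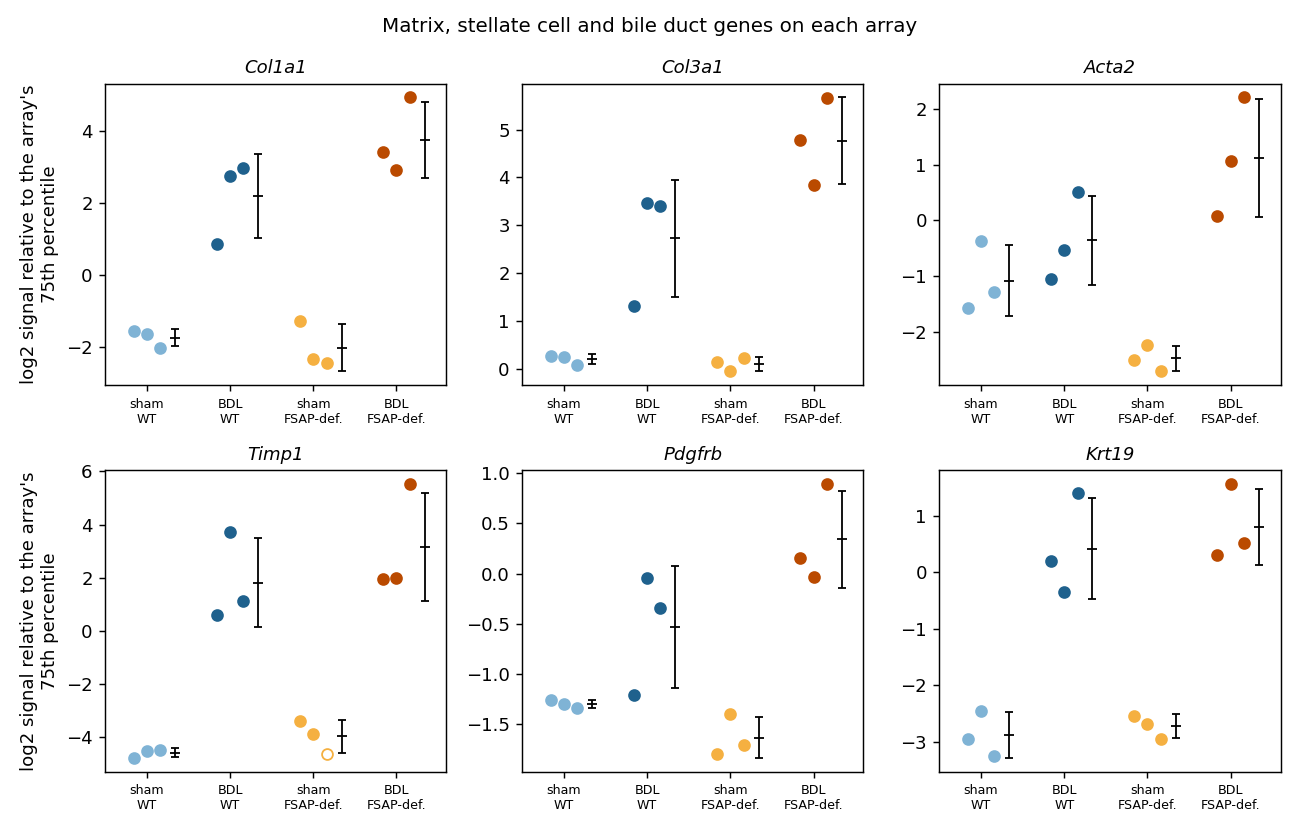
Log2 signal of Col1a1, Col3a1, Acta2, Timp1, Pdgfrb and Krt19 on each of the 12 arrays, relative to the array's 75th percentile, by group (filled points are well above background, hollow points are not, and the dash and bar give the mean ± SD, n = 3). Col1a1 averages -1.75 in WT sham livers, 2.19 in WT livers after BDL, -2.03 in FSAP-deficient sham livers and 3.75 in FSAP-deficient livers after BDL.

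Cholangiocyte markers rose in 20 and fell in 3 of 31 (21 and 4 adjusted over the list alone, median 1.98, within slide 1 1.98, adjusted p = 0.129 with an estimated correlation), with the transcription factor Sox9 at 3.97, the collagen receptor Ddr1 at 5.16 and the epithelial factor Elf3 at least 41.9-fold higher. Of 36 macrophage markers, 28 rose and 0 fell (29 and 1 adjusted over the list alone, median 1.43, within slide 1 1.47, adjusted p = 0.226 with an estimated correlation). Trem2, a lipid-sensing receptor, was at 3.89, the scavenger receptor Marco at 3.97, and Gpnmb at least 16.3-fold higher. Neutrophil markers rose in 14 of 22 (15 adjusted over the list alone, median 2.42, within slide 1 1.90, adjusted p = 0.269 with an estimated correlation), including the granule protease Prtn3 (3.91) and Chil3 (5.27). Cytokines and chemokines rose in 16 and fell in 7 of 36 (18 and 7 adjusted over the list alone, median 0.97, within slide 1 0.25, adjusted p = 0.269 with an estimated correlation), with Ccl2, which attracts monocytes, at 5.18. Acute-phase genes rose in 18 and fell in 2 of 39 (19 and 2 adjusted over the list alone, median 1.18, within slide 1 1.33, adjusted p = 0.51 with an estimated correlation), among them the serum amyloids Saa1 (4.29) and Saa2 (4.09) and lipocalin Lcn2 (6.07). p53 targets rose in 14 and fell in 1 of 23 (16 and 1 adjusted over the list alone, median 0.92, within slide 1 0.82, adjusted p = 0.0938 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a (5.97). Lymphocyte markers and interferon genes moved down. T and NK cell markers fell in 13 and rose in 2 of 27 (13 and 4 adjusted over the list alone, median -1.12, within slide 1 -0.79, adjusted p = 0.578 with an estimated correlation, the call ended without replicate 1 of the WT sham group), with the interleukin 2 receptor chain Il2rb at least 3.47-fold lower. B cell markers fell in 9 and rose in 2 of 15 (9 and 2 adjusted over the list alone, median -1.28, within slide 1 -1.15, adjusted p = 0.431 with an estimated correlation), with Ms4a1, the B cell antigen CD20, at least 2.63-fold lower. Interferon response genes fell in 15 of 38 (18 adjusted over the list alone, median -0.74, within slide 1 -0.78, adjusted p = 0.558 with an estimated correlation), among them Ifit3 (-2.45) and Ifit1 (-1.91).

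Metabolic lists fell together. Cytochrome P450 enzymes fell in 24 and rose in 1 of 35 (25 and 1 adjusted over the list alone, median -1.85, within slide 1 -2.06, adjusted p = 0.226 with an estimated correlation), with Cyp2c37 at -5.04. Phase II enzymes fell in 22 and rose in 3 of 45 (22 and 3 adjusted over the list alone, median -1.02, within slide 1 -0.97, adjusted p = 0.51 with an estimated correlation), with the sulfotransferase Sult3a1 at -9.90. Fatty acid oxidation genes fell in 26 of 33 (27, and 1 up, adjusted over the list alone, median -1.12, within slide 1 -1.06, adjusted p = 0.226 with an estimated correlation), with the lipid-sensing receptor Ppara at -3.20. Lipogenesis genes fell in 16 and rose in 2 of 26 (16 and 3 adjusted over the list alone, median -1.4, within slide 1 -1.28, adjusted p = 0.394 with an estimated correlation), with Thrsp at -4.90. Cholesterol synthesis genes fell in 11 of 22 (16 adjusted over the list alone, median -1.68, within slide 1 -2.82, adjusted p = 0.51 with an estimated correlation), with Sc5d at -2.57. Bile acid synthesis genes fell in 11 and rose in 1 of 19 (11 and 1 adjusted over the list alone, median -0.67, within slide 1 -0.72, adjusted p = 0.269 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase of that pathway, fell by 4.75, and Cyp7a1, its rate-limiting enzyme, stood at -0.75 (adjusted p = 0.289). Urea cycle, amino acid and gluconeogenesis genes fell in 20 and rose in 2 of 41 (21 and 2 adjusted over the list alone, median -0.58, within slide 1 -0.63, adjusted p = 0.423 with an estimated correlation), with Otc, a urea cycle enzyme, at -1.93. Clock genes fell in 13 and rose in 2 of 18 (13 and 3 adjusted over the list alone, median -1.58, within slide 1 -1.82, adjusted p = 0.226 with an estimated correlation), with Dbp at -4.41 and Per3 at -3.27. Hepatocyte markers fell in 13 and rose in 1 of 34 (13 and 1 adjusted over the list alone, median -0.46, and -0.12 with the call ended within slide 1, adjusted p = 0.563 with an estimated correlation), and their call also ended with quantile normalization (-0.21) and without replicate 3 of the WT BDL group (-0.30). Female-biased liver genes fell in 11 of 22 (12 adjusted over the list alone, median -2.70, within slide 1 -2.53, adjusted p = 0.563 with an estimated correlation), with A1bg at least 622-fold lower. Male-biased ones fell in 9 and rose in 1 of 20 (9 and 1 adjusted over the list alone, median -1.24, within slide 1 -1.22, adjusted p = 0.629 with an estimated correlation), and the major urinary protein Mup21 fell by 8.39. The call of the male-biased list ended with normexp (-0.75), with median scaling (-1.39) and in 4 of the 6 cases with 1 array left out.

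Of the 36 lists, 27 moved in WT, 13 up and 14 down. None passed with an estimated correlation (camera, lowest adjusted p = 0.0938). The fry test, which asks whether a list changed at all and not whether it did more than other genes, called 24, and 8467 genes had an unadjusted p under 0.05. Cell cycle genes were positive in 46 of 50, with 2 rises and 1 fall (0 and 1 adjusted over the list alone, median 1.28, adjusted p = 0.616 with an estimated correlation), but their call ended within slide 1 (-0.37) and without replicate 2 of the WT BDL group (0.19), the array on which the list stood at 3.38 above the WT sham mean. Coagulation and fibrinolysis did not move (13 rises, 11 falls of 43, 15 and 11 adjusted over the list alone, median 0.14, within slide 1 0.51). Nor did bile transport (3 and 7 of 22, 3 and 8, median -0.16, within slide 1 0.16), complement (9 and 4 of 27, 9 and 4, median 0.13, within slide 1 0.48) or MHC class II (0 and 2 of 9, 0 and 0, median -0.98, within slide 1 -0.65) move. The remaining lists that did not were ER stress (2 and 4 of 28, 2 and 4, median -0.21, within slide 1 -0.16), ribosomal proteins (0 and 0 of 43, 0 and 0, median 0.02, within slide 1 0.20), sinusoidal endothelium (4 and 6 of 31, 4 and 6, median -0.23, within slide 1 -0.45), erythroid cells (2 and 4 of 19, 1 and 4, median 0.58, within slide 1 0.09) and pancreas (3 and 1 of 12, 3 and 1, median 0.37, within slide 1 0.79). In the test with slide as a block, coagulation (adjusted p = 0.0355) and complement (adjusted p = 0.0064) passed upward and sinusoidal endothelium (adjusted p = 0.00487) downward, so whether these 3 moved depends on the slide term. With slide as a block, 3304 genes changed and 2942 of the 6415 kept their call. Within slide 1, every called gene with a value, 6414 of 6415, moved the same way, but these are in part the same arrays.

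The second comparison asked the same of FSAP-deficient livers. Many matrix and myofibroblast genes rose, as did genes of bile duct cells, macrophages, the cell cycle and MHC class II, and many hepatocyte genes fell. Their lists moved with the preset correlation, but none of these did with an estimated one. Col1a1 rose 55.1-fold (log2 change 5.78, SE 0.61, adjusted p = 7.25e-05), Acta2 rose 12.1-fold (3.6, SE 0.54, adjusted p = 0.000508) and Timp1 140.0-fold (7.13, SE 0.97). The MHC class II chain H2-Ab1, which presents antigen to helper T cells, rose 7.0-fold (2.81, SE 0.47). The interaction did not pass for Acta2 (2.88, adjusted p = 0.158) or H2-Ab1 (3.91, adjusted p = 0.0944). Sult2a8, a sulfotransferase, fell by 6.20 (SE 0.34). In all, 7624 genes changed, 3166 up and 4458 down, of which 2372 rose and 1833 fell at least 2-fold, and 1606 had no gene symbol. The share that rose was 41.5%, and 28.7% under median scaling. The groups did not overlap for 47.5% of genes, where chance gives 10%.

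Of 20 collagens, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 2.56 and 2.66 within slide 3 (adjusted p = 0.159 with an estimated correlation). Col1a2 rose 17.4-fold and Col3a1 25.3-fold. Matrix glycoproteins rose in 29 and fell in 2 of 39 (30 and 2 adjusted over the list alone, median 1.99, within slide 3 1.72, adjusted p = 0.154 with an estimated correlation), with Thbs1 (5.02), Mgp (4.39) and Fbln2 (3.93), while Fn1 stood at -0.19 (adjusted p = 0.572). Remodelling enzymes rose in 26 and fell in 2 of 35 (26 and 2 adjusted over the list alone, median 2.31, within slide 3 2.38, adjusted p = 0.115 with an estimated correlation), with Mmp7 at 6.33 and Adam8 at 4.93. TGF-beta and PDGF genes rose in 20 of 36 (21 adjusted over the list alone, median 0.85, within slide 3 0.82, adjusted p = 0.0654 with an estimated correlation). Pdgfrb rose 3.93-fold, Ccn2, connective tissue growth factor, by 2.92, and Tgfb1 2.53-fold, though Tgfb1 stood at 0.80 and did not pass without the arrays with Y-linked signal. Stellate and myofibroblast markers rose in 22 and fell in 3 of 34 (23 and 4 adjusted over the list alone, median 1.85, within slide 3 1.69, adjusted p = 0.267 with an estimated correlation). Mesothelial and adipose markers rose in 12 and fell in 1 of 15 (13 and 1 adjusted over the list alone, median 1.61, within slide 3 1.55, adjusted p = 0.101 with an estimated correlation). Cholangiocyte markers rose in 21 and fell in 2 of 31 (21 and 3 adjusted over the list alone, median 2.93, within slide 3 3.06, adjusted p = 0.0628 with an estimated correlation), with Krt19 11.5-fold higher and Spp1, osteopontin, 41.7-fold higher.

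Macrophage markers rose in 33 of 36 (34 adjusted over the list alone, median 2.21, within slide 3 2.26, adjusted p = 0.0654 with an estimated correlation), with Trem2 at 4.23 and the integrin Itgax at 4.13. Neutrophil markers rose in 16 of 22 (16 adjusted over the list alone, median 3.24, within slide 3 2.31, adjusted p = 0.159 with an estimated correlation). Cytokines and chemokines rose in 23 and fell in 3 of 36 (23 and 4 adjusted over the list alone, median 2.21, within slide 3 2.00, adjusted p = 0.0654 with an estimated correlation). Ccl2 rose 73.1-fold and the monocyte chemokine Ccl8 at least 26.4-fold. Of 9 MHC class II genes, 7 rose (7 adjusted over the list alone, median 2.77, within slide 3 2.71, adjusted p = 0.25 with an estimated correlation), including Cd74, the invariant chain (2.81), and H2-DMb1, which loads peptide (2.91). Cell cycle genes rose in 42 and fell in 3 of 50 (45 and 3 adjusted over the list alone, median 3.00, within slide 3 2.89, adjusted p = 0.309 with an estimated correlation), with the topoisomerase Top2a at least 9.43-fold higher. The p53 list rose in 14 of 23 (16 adjusted over the list alone, median 0.91, within slide 3 1.06) and was the only list that passed with an estimated correlation (adjusted p = 0.0347), with Cdkn1a at least 60.6-fold higher. Interferon response genes rose in 7 and fell in 1 of 38 (6 and 0 adjusted over the list alone, median 0.36, adjusted p = 0.674 with an estimated correlation), and T and NK cell markers in 7 and 2 of 27 (4 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.654 with an estimated correlation). Both calls ended within slide 3 (0.16 and 0.33), without replicate 1 of the sham group (0.10 and 0.13) and without replicate 1 of the BDL group (-0.11 and 0.19).

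Hepatocyte markers fell in 23 of 34 (23 adjusted over the list alone, median -0.78, within slide 3 -0.81, adjusted p = 0.309 with an estimated correlation). P450 enzymes fell in 21 and rose in 1 of 35 (24 and 1 adjusted over the list alone, median -1.89, within slide 3 -2.23, adjusted p = 0.154 with an estimated correlation). Phase II enzymes fell in 21 and rose in 6 of 45 (21 and 7 adjusted over the list alone, median -0.87, within slide 3 -0.73, adjusted p = 0.629 with an estimated correlation), with the call ended under quantile normalization (-0.49) and without replicate 3 of the BDL group (-0.62). Fatty acid oxidation genes fell in 23 and rose in 1 of 33 (23 and 1 adjusted over the list alone, median -0.96, within slide 3 -0.96, adjusted p = 0.252 with an estimated correlation). Urea cycle and amino acid genes fell in 32 of 41 (36 adjusted over the list alone, median -1.12, within slide 3 -1.03, adjusted p = 0.152 with an estimated correlation), with Glul, glutamine synthetase, at -2.20. Bile acid synthesis genes fell in 14 of 19 (14 adjusted over the list alone, median -0.94, within slide 3 -0.94, adjusted p = 0.154 with an estimated correlation), with Cyp8b1 at -4.08 and Cyp7a1 at -0.30 (adjusted p = 0.672). Cholesterol synthesis genes fell in 10 of 22 (12 adjusted over the list alone, median -1.55, within slide 3 -2.04, adjusted p = 0.649 with an estimated correlation). Clock genes fell in 5 of 18 (5 adjusted over the list alone, median -0.97, within slide 3 -0.87, adjusted p = 0.243 with an estimated correlation), with the call ended without replicate 2 of the BDL group (-0.90). Male-biased genes fell in 11 of 20 (11 adjusted over the list alone, median -1.50, and -0.82 with the call ended within slide 3, adjusted p = 0.649 with an estimated correlation). Without replicate 1 of the sham group (-0.90) or replicate 3 of the BDL group (-1.04) that call ended too.

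In FSAP-deficient livers 24 of the 36 lists moved, 15 up and 9 down, of which 1 passed with an estimated correlation, and fry called 25. Coagulation and fibrinolysis did not (12 rises, 14 falls of 43, 12 and 16 adjusted over the list alone, median -0.17 but mean 0.48 and test upward, within slide 3 -0.27), nor did bile transport (4 and 9 of 22, 4 and 9, median -0.30, within slide 3 -0.49), although the uptake carrier Slco1a1 fell by 6.93. The other lists that did not move were lipogenesis (5 and 12 of 26, 5 and 12, median -0.61, within slide 3 -1.10), the acute phase (9 and 7 of 39, 9 and 7, median 0.41, within slide 3 0.29), complement (5 and 8 of 27, 5 and 9, median -0.30, within slide 3 -0.24), and ER stress (2 and 5 of 28, 2 and 5, median -0.51, within slide 3 -0.21). Nor did ribosomal proteins (0 and 1 of 43, 0 and 0, median 0.01, mean -0.02, within slide 3 0.10), female-biased genes (0 and 2 of 22, 0 and 2, median -1.81, within slide 3 -3.26) or sinusoidal endothelium (7 and 3 of 31, 7 and 3, median 0.15, within slide 3 0.23) move. B cells (1 and 4 of 15, 1 and 4, median -0.55, within slide 3 -0.67), erythroid cells (2 and 4 of 19, 2 and 4, median 0.31, within slide 3 0.44) and pancreas (2 and 2 of 12, 2 and 2, median -0.11 but mean 0.68 and test upward, within slide 3 0.02) complete them. In the test with slide as a block, female-biased genes (adjusted p = 2.05e-07) and B cells (adjusted p = 0.048) passed downward and sinusoidal endothelium (adjusted p = 0.0447) upward. The female-biased list stood at -5.63 on replicate 1 of the sham group, the array with Y-linked signal on another slide, and at -0.50 and -0.05 on the other sham arrays. With slide as a block 4190 genes changed and 3908 of the 7624 kept their call. Within slide 3, every called gene with a value, 7622 of 7624, moved the same way, but these are in part the same arrays.

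**Figure D3:**
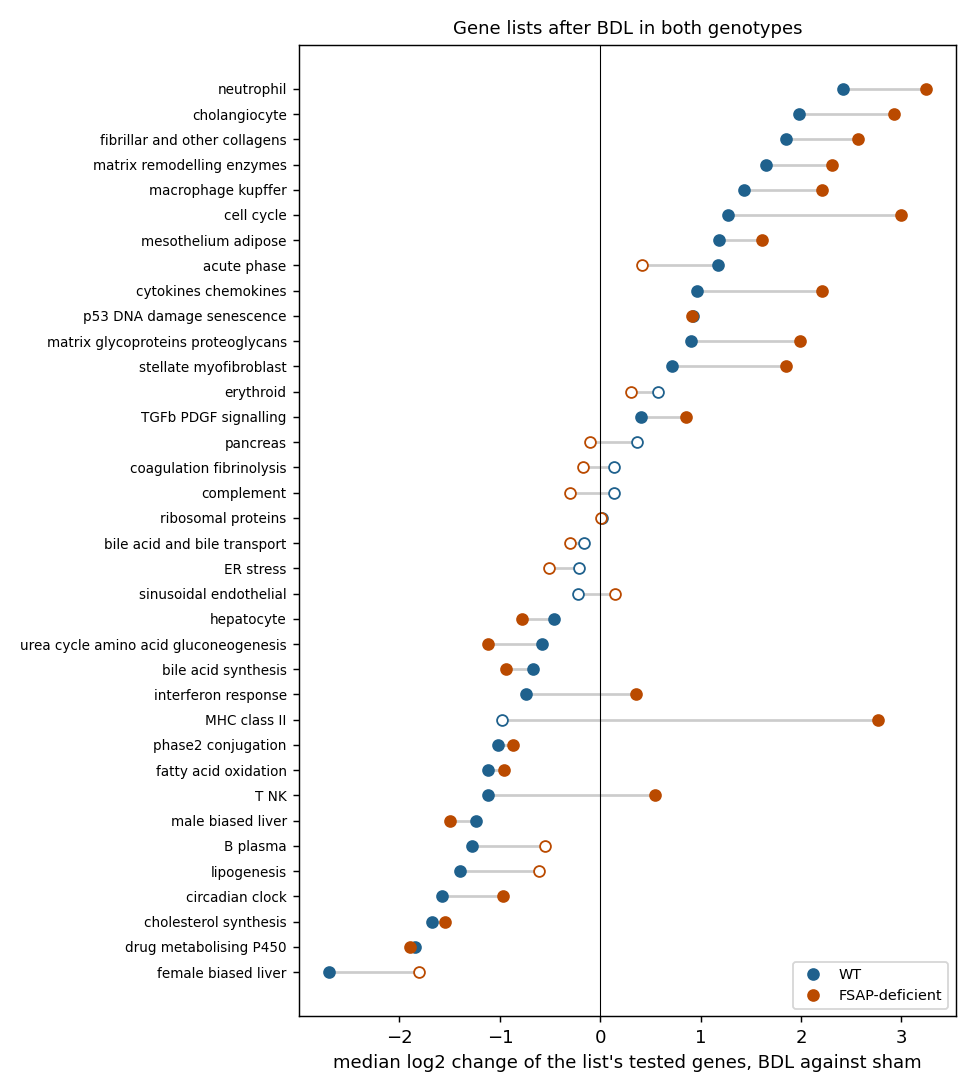
Median log2 change after BDL of each gene list in WT and in FSAP-deficient livers (filled points passed camera at an adjusted p of 0.05 with the preset correlation). The MHC class II median is -0.98 in WT and 2.77 in FSAP-deficient livers, and the macrophage median is 1.43 and 2.21.

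Across the 19531 genes, the BDL effects in the 2 genotypes, which share no array, correlated at r = 0.805 and rho = 0.745, with a covariance of 0.989, and the slope of the FSAP-deficient on the WT effect was 0.844. Noise in the WT effect pulls such a slope toward 0, so it does not show a weaker response without FSAP. The median absolute change was 0.444 in WT and 0.486 in FSAP-deficient livers. Genes are not independent replicates, so no p-value is given. With slide as a block r was 0.687. Of the genes that changed in both genotypes, 2024 rose and 2647 fell in both, where independent lists of those sizes would share 479.5 and 789.1, and 35 moved in opposite directions.

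**Figure D4:**
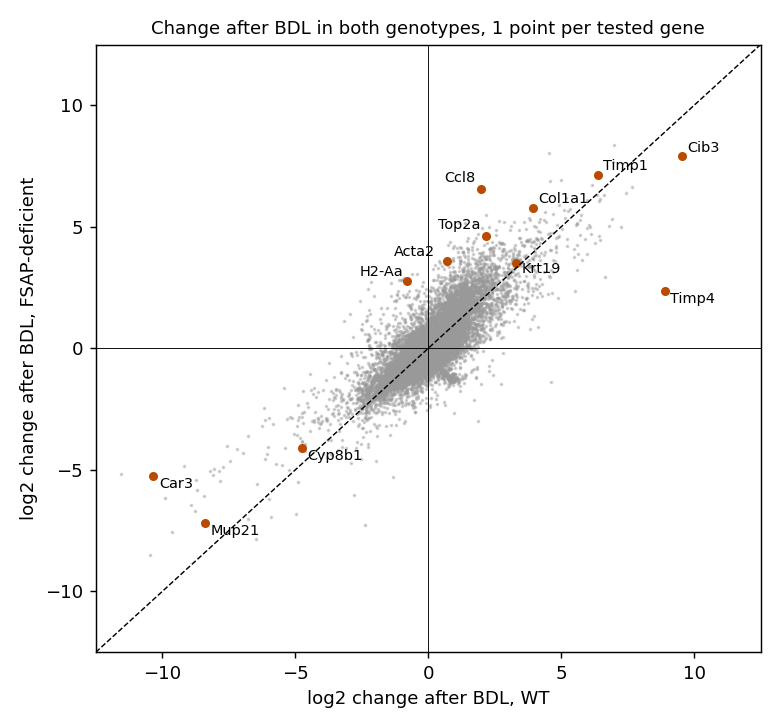
Log2 change after BDL in WT (x axis) against FSAP-deficient livers (y axis), 1 point per tested gene, with the line of equal change dashed and genes named in the text or by the rule labelled. The correlation across genes is 0.805, and H2-Aa and Ccl8 lie above the line and Timp4 below it.

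The third comparison asked what the loss of FSAP changed without ligation. Besides both Habp2 probes, 1 gene differed between sham livers, Sptbn4, a spectrin of neurons (7:28141402-28141461), which was at least 2.52-fold higher (adjusted p = 0.0417) and was named after its value was seen. It was not well above background on any WT sham array, and its call ended with slide as a fixed block (adjusted p = 0.436) or a random one, with normexp, quantile normalization, the series matrix, no filter, only the groups compared, a trended robust variance and without the arrays with Y-linked signal. In all, 3 probes or genes changed (1540 at an unadjusted p under 0.05), 2 or 3 when 1 array was left out, and 168 with array weights. Fibrosis genes did not pass. Acta2 was at -1.4 (adjusted p = 0.532), Timp1 at 0.61, Cyp7a1 at -0.43, and Col1a1, Col1a2, Col3a1, Fn1, Tgfb1, Pdgfrb and Krt19 lay between -0.33 and 0.16. With slide as a block Timp1, Cyp7a1, Fn1, Tgfb1 and Krt19 changed sign. The groups did not overlap for 17.1% of genes, where chance gives 10%.

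No list member passed in the lists described for sham livers, though some lists moved as a whole. Male-biased liver genes were positive in 20 of 20 (0 passed, 0 adjusted over the list alone, median 1.48, adjusted p = 0.588 with an estimated correlation), and female-biased ones in 0 of 22 (0 passed, 0 adjusted over the list alone, median -2.14, adjusted p = 0.588 with an estimated correlation), with Hamp2, a hepcidin copy, at -3.54 (adjusted p = 0.325). Replicate 1 of the FSAP-deficient sham group, which carried Y-linked signal, stood at 3.57 for the male-biased and -5.63 for the female-biased list, and the other FSAP-deficient sham arrays at 0.73 and 0.25 and at -0.50 and -0.05. Without the arrays with Y-linked signal the medians were 0.50 and -0.40. MHC class II genes were positive in 0 of 9 (0 passed, 0 adjusted over the list alone, median -0.87, and -0.27 with normexp, adjusted p = 0.588 with an estimated correlation) and interferon genes in 3 of 38 (0 and 0, median -0.42, adjusted p = 0.592 with an estimated correlation). The interferon median was -0.20 without replicate 1 of the FSAP-deficient sham group, the array on which the list stood at -0.79, against -0.11 and -0.26 on the others. Lipogenesis had a median of -0.32 (-0.19 without replicate 2 of the FSAP-deficient sham group, -0.87 with slide as a block), with 3 members lower adjusted over the list alone (adjusted p = 0.588 with an estimated correlation), among them Scd1, a stearoyl-CoA desaturase whose gene lies on chromosome 19 like the targeted one, at -1.25 (adjusted p = 0.226). Of 36 lists 17 moved, 2 up and 15 down (10 without replicate 1 of the FSAP-deficient sham group), but 0 with an estimated correlation (lowest adjusted p = 0.588) and 0 by fry. The calls of the male-biased (0.78), female-biased (-0.41), MHC class II (-0.20) and interferon (-0.20) lists ended with slide as a block. In 6 lists the median, mean and test differed in sign (matrix remodelling, TGF-beta and PDGF, coagulation, bile transport, acute phase and ribosomal proteins).

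The fourth comparison, which bears on the question in the title, set FSAP-deficient against WT livers after BDL. Besides Habp2, several MHC class II genes were higher in FSAP-deficient livers. Their list did not move with an estimated correlation. The calls of those named here ended with slide as a block and without the arrays with Y-linked signal. H2-Aa (17:34421285-34421344) was 8.99-fold higher (3.17, SE 0.49), H2-Eb1 8.80-fold, H2-Ab1 7.90-fold and H2-DMb1 7.63-fold, each with an adjusted p of 0.0406. For H2-Aa, H2-Eb1 and H2-Ab1 all 3 FSAP-deficient arrays stood above all 3 WT arrays. Ccl8, a chemokine that attracts monocytes and T cells, was 9.11-fold higher (3.19, SE 0.50), and Timp4 was lower by 6.33 on the log2 scale (-6.33, SE 0.85, adjusted p = 0.0347), well above background on 2 of the 3 FSAP-deficient arrays. The collagens and Acta2 were higher in mean without passing the test. Col1a1 stood at 1.56 (SE 0.61, adjusted p = 0.32), Col3a1 at 2.04 (SE 0.55, adjusted p = 0.156), Col1a2 at 1.32 (adjusted p = 0.37) and Acta2 at 1.48 (SE 0.54, adjusted p = 0.283).

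In all, 42 genes, both Habp2 probes included, differed, 24 higher and 18 lower (2515 at an unadjusted p under 0.05), 21 and 16 of them at least 2-fold, and 9 had no symbol. The share that was higher was 57.1%, and 43.1% under median scaling. The groups did not overlap for 15.6% of genes, where chance gives 10%. Other genes that were higher included the interferon-induced Ifi44 (2.05), Clec7a, the beta-glucan receptor dectin-1 (1.76), Slamf9 (1.76), Sema4d (1.55) and the p53 target Phlda3 (1.13). Lower were the muscle protein Myom3 (-3.50), the cadherin Celsr1 (-1.86), the aspartate aminotransferase Got1 (-1.8), Ube2v2 (-1.77), the polarity protein Pard6g (-1.77, adjusted p = 0.0018), the sialidase Neu3 (-1.33), Pwwp3a (-1.22), Chst8 (-1.11), the urea cycle enzyme Asl (-1.06) and Atl2 (-0.94). Timp1 (1.34), Tgfb1 (0.52), Pdgfrb (0.87), Krt19 (0.38), Fn1 (-0.53) and Cyp7a1 (0.01) did not pass (adjusted p from 0.262 to 0.994), and Cyp7a1 turned to -0.09 under median scaling. Named after their values were seen, Pdcd1, an inhibitory receptor of T cells (at least 4.04-fold, not well above background on any WT array), and Leap2, a liver peptide (1.55), were also higher.

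Of 9 MHC class II genes 5 were higher (8 adjusted over the list alone, median 2.93, adjusted p = 0.232 with an estimated correlation, 0.0164 by fry). Interferon genes were positive in 35 of 38, of which 1 passed (12 adjusted over the list alone, median 0.83, adjusted p = 0.319 with an estimated correlation). Macrophage markers had 1 higher (11, and 1 lower, adjusted over the list alone, median 0.54, adjusted p = 0.293 with an estimated correlation). Cytokines and chemokines had 1 higher (9 adjusted over the list alone, median 0.42, adjusted p = 0.232 with an estimated correlation), and T and NK cell markers had 0 (9 adjusted over the list alone, median 0.79, adjusted p = 0.319 with an estimated correlation), with Ccl5, a T cell chemokine, at 3.41 (adjusted p = 0.066). Urea cycle and amino acid genes had 2 lower, Got1 and Asl (14 adjusted over the list alone, median -0.54, adjusted p = 0.232 with an estimated correlation, 0.0325 by fry). Cell cycle genes were positive in 48 of 50 (0 passed, 2 adjusted over the list alone, median 1.34, adjusted p = 0.319 with an estimated correlation). Their median was 0.53 without replicate 1 of WT and 2.37 without replicate 2, since the WT arrays stood at -0.37, 3.38 and 0.63 and the FSAP-deficient ones at 2.53, 2.95 and 2.18. Collagens were positive in 17 of 20 (0 and 0, median 0.71, adjusted p = 0.363 with an estimated correlation). Glycoproteins were positive in 34 of 39 (0 and 0, median 0.67, adjusted p = 0.319 with an estimated correlation), and stellate markers in 28 of 34 (0 passed, 1 adjusted over the list alone, median 0.66, adjusted p = 0.319 with an estimated correlation). Remodelling enzymes had 1 lower, Timp4, against a median of 0.50 (1 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation). Acute-phase genes were positive in 3 of 39 (0 and 0, median -0.60, adjusted p = 0.319 with an estimated correlation). The p53 targets had a median of 0.22 and did not move, and male-biased genes were positive in 15 of 20 (0 passed, 2 adjusted over the list alone, median 1.17, adjusted p = 0.582 with an estimated correlation). Of 36 lists 20 moved, 15 up and 5 down, 0 of them with an estimated correlation (lowest adjusted p = 0.232) and 2 by fry, and in the neutrophil and pancreas lists median, mean and test differed in sign.

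Single arrays weighed on these calls. Without replicate 1 of WT after BDL 6 genes differed, without replicates 2 and 3 of that group 92 and 95, and without replicate 1 of FSAP-deficient after BDL 10. Ube2v2 and Pard6g passed whichever array was left out. Of the 23 named genes besides Habp2 that passed, 0 kept their call under every other alternative. H2-DMb1 missed the threshold only without replicate 1 of WT, and the other named genes in 2 to 6 of the 6 cases, with H2-Aa, H2-Ab1 and H2-Eb1 missing it without replicates 1 and 2 of either genotype. Slide as a block left 2 genes, both lower and called in the main setting, which may be the Habp2 probes. With that block and without the arrays with Y-linked signal H2-Aa was at 3.26 (SE 1.17) and 2.11, against 3.17 (SE 0.49). The interferon median fell from 0.83 to 0.35 and the T and NK median from 0.79 to 0.42 without replicate 1 of FSAP-deficient, an array with Y-linked signal, and both kept their calls. Remodelling enzymes lost theirs without replicate 1 of WT (0.19) or replicate 3 of FSAP-deficient (0.32). Without replicate 1 of WT the glycoprotein median was 0.34 and the stellate median 0.35. The call of the collagen list ended with slide as a block (0.49) and without replicate 3 of FSAP-deficient (0.50), that of cytokines (0.38) and stellate markers (0.33) with slide as a block, and the male-biased median turned to -0.18 without the arrays with Y-linked signal.

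**Figure D5:**
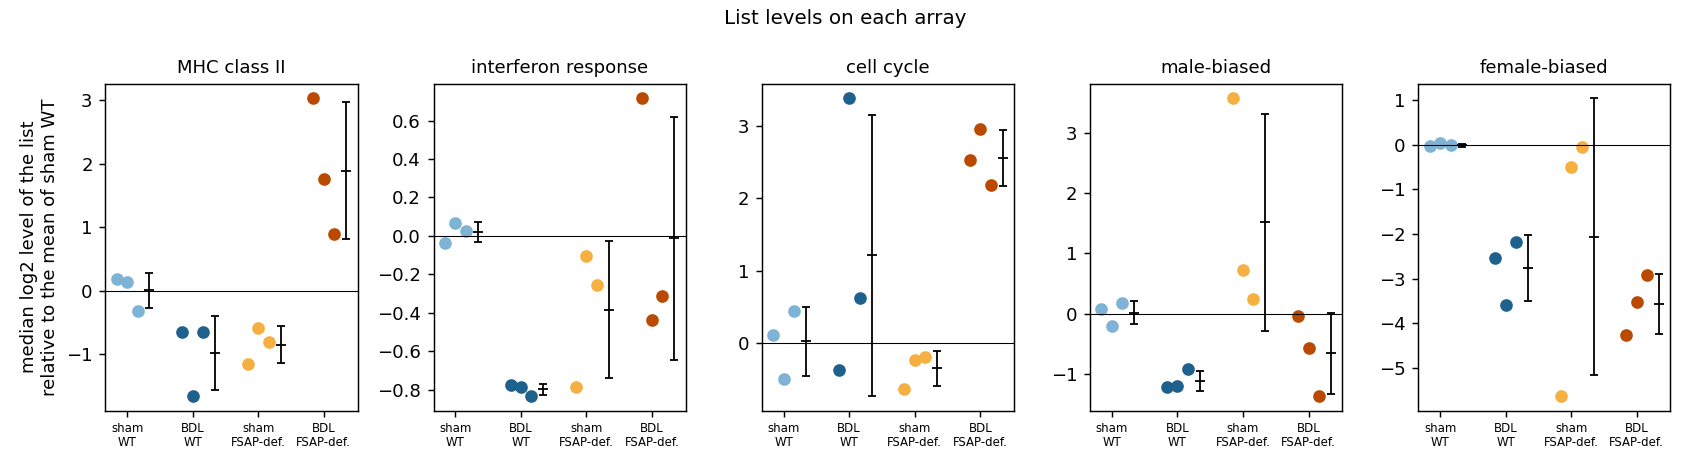
Median level of 5 gene lists on each array, as log2 change against the mean of the WT sham arrays, by group (1 point per array). MHC class II stands at 3.02, 1.75 and 0.89 on the FSAP-deficient BDL arrays and between -1.65 and -0.65 on the WT BDL arrays.

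Averaged over both surgeries, FSAP-deficient livers differed from WT in Habp2 (adjusted p = 1.102e-06) and its second probe, with the bounds given above for each surgery, and in Pard6g, which was lower at -0.97 (SE 0.11, adjusted p = 0.0206). These were all 3 that passed (1517 at an unadjusted p under 0.05). Pard6g missed the threshold when any 1 of 11 of the 12 arrays was left out. Acta2 was at 0.04, Col1a1 at 0.64 (adjusted p = 0.766), Col1a2 at 0.60, Col3a1 at 0.97 (adjusted p = 0.612), Fn1 at -0.35, Timp1 at 0.98, Tgfb1 at 0.09, Pdgfrb at 0.27, Krt19 at 0.27 and Cyp7a1 at -0.21, none past the threshold. With slide as a block Col1a1, Col1a2, Col3a1, Acta2, Pdgfrb and Cyp7a1 changed sign. MHC class II genes had a median of 1.02 (0.62 without the arrays with Y-linked signal, 0 passed, 7 adjusted over the list alone, adjusted p = 0.542 with an estimated correlation), male-biased genes 1.37 (0 passed, 5 adjusted over the list alone, adjusted p = 0.542 with an estimated correlation) and urea cycle genes -0.29 (0 passed, 3 lower adjusted over the list alone, adjusted p = 0.542 with an estimated correlation). The male-biased median was 0.81 without replicate 1 of the FSAP-deficient sham group, and its call ended without the arrays with Y-linked signal (0.27) and with a term for them (0.12). The urea cycle median was -0.16 without replicate 3 of FSAP-deficient after BDL and -0.54 without the arrays with Y-linked signal, and it kept its call. In all 20 of 36 lists moved, 11 up and 9 down, 0 with an estimated correlation (lowest adjusted p = 0.542) and 0 by fry, and 12 without replicate 1 of WT after BDL. In 5 lists median, mean and test differed in sign.

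The interaction asked whether the response to BDL itself differed between genotypes. Sema4d, a semaphorin of immune cells, passed with a fitted difference of 3.08 (adjusted p = 0.0244), but no FSAP-deficient sham array was well above background, so its size is not measured. It was at least 8.48-fold higher after BDL in FSAP-deficient livers and 1.37-fold higher in WT (adjusted p = 0.164). The predicted transcript LOC100041034 passed at 1.78 (SE 0.20, adjusted p = 0.0244), and it was named after its value was seen. Under slide as a fixed block the fitted values were 3.30 (adjusted p = 0.104) and 1.73 (SE 0.28, adjusted p = 0.111), so both calls ended, as they did without a filter and with the replicate block. Acta2 differed by 2.88 (SE 0.76, adjusted p = 0.158), Col1a1 by 1.84 (adjusted p = 0.385), Col3a1 by 2.13 (adjusted p = 0.272), Col1a2 by 1.43 (adjusted p = 0.474), Pdgfrb by 1.20 (adjusted p = 0.264), Tgfb1 by 0.84 (adjusted p = 0.396), Timp1 by 0.74, Cyp7a1 by 0.45, Krt19 by 0.22, Fn1 by -0.37 and Habp2 by a fitted -1.0, none past the threshold, so a larger rise of these genes without FSAP was not shown.

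Among the 36 lists, MHC class II genes had the highest interaction median, 3.79 (0 passed, 8 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation, 0.029 by fry), with H2-Ab1 at 3.91 and H2-DMb1 at 3.80 (both adjusted p = 0.0944). Interferon genes stood at 1.23 (0 passed, 15 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), and at 0.73 without replicate 1 of FSAP-deficient after BDL. T and NK cell markers stood at 1.47 (0 passed, 13 and 2 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation, 0.44 with normexp) and cell cycle genes at 1.85 (0 passed, 1 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation), the latter at 1.14 and 2.86 without replicates 1 and 2 of WT after BDL. Macrophage markers stood at 0.87 (0 passed, 11 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), with Itgax at 3.05 (adjusted p = 0.0922). Collagens stood at 0.85 (0 and 0, adjusted p = 0.492 with an estimated correlation, the call ended at 0.59 without replicate 3 of FSAP-deficient after BDL), stellate markers at 0.81 (0 passed, 6 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation) and the acute phase at -0.72 (0 and 0, adjusted p = 0.492 with an estimated correlation). Of 36 lists 23 moved, 19 up and 4 down, 0 with an estimated correlation (lowest adjusted p = 0.238) and 1 by fry, and in 2 lists median, mean and test differed in sign. At an unadjusted p under 0.05 there were 2674 genes. Sema4d missed the threshold when any 1 of 7 arrays was left out, and between 0 and 22 genes passed when 1 array was left out. The count rose to 264 without the arrays with Y-linked signal and to 365 with a term for them.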

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

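The 3 tests of MHC class II explanations below were chosen after the result was seen, while the counts of other splits were fixed before it. Except for the last paragraph, the results concern the interaction, that is, how far the response to BDL differed between FSAP-deficient and WT livers. Groups of 3 arrays were not searched for single outlying arrays.

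A pair of genes differed between genotypes in their response to BDL, LOC100041034 by 1.78 on the log2 scale and Sema4d by a fitted 3.08, whose size is not measured because no FSAP-deficient sham array was well above background. Both missed the threshold with slide as a block. Of 100 drawn splits of the arrays, 4 gave as many genes as the real 2, the real split included, and another split reached 8. That share is under the 0.05 fixed beforehand. It rests on a draw of the possible splits and on arrays that differ in Y-linked signal, so it does not exclude chance. The splits take no account of slides, which follow the groups, so slide stays open for this count. Among the 36 lists 23 differed with the preset correlation, and none did with an estimated one (camera, 0 of 36; 1 by fry). Here 13 of 100 splits gave as many lists, the highest other being 29, so chance cannot be excluded for their number.

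Lists with a more positive response in FSAP-deficient livers were led by MHC class II, at a median of 3.79. Immune and cycling lists were also among them, with the cell cycle at 1.85, T and NK cells at 1.47, the interferon response at 1.23, macrophages at 0.87 and cytokines at 0.65. Matrix lists stood at 0.85 for collagens, 0.81 for stellate cells, 0.72 for glycoproteins, 0.50 for mesothelium and adipose tissue, 0.42 for remodelling enzymes and 0.28 for TGF-beta and PDGF signalling. Female-biased genes stood at 1.47, clock genes at 0.49, lipogenesis at 0.46, sinusoidal endothelium at 0.36, fatty acid oxidation at 0.32, cholangiocytes at 0.22 and p53 targets at 0.12. The fatty acid oxidation median turned negative with slide as a block. The female-biased list stood at -5.63 on the FSAP-deficient sham array with Y-linked signal and at -0.50 and -0.05 on the others. Its interaction missed the threshold at 0.46 without the arrays with Y-linked signal, turned to -0.30 with slide as a block, and was 2.49 with a term for Y-linked signal. The cell cycle ranged from 1.14 to 2.86 when 1 array was left out. A more negative response was seen in the acute phase at -0.72, urea cycle and amino acid genes at -0.44, bile transport at -0.34 and hepatocyte markers at -0.30.

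MHC class II genes were higher in FSAP-deficient than in WT livers after BDL, by 2.87 (SE 0.52) in the group mean of each array's list median. Of 9 members 5 passed, and the list did not move with an estimated correlation (adjusted p = 0.232). With a term for Y-linked signal the difference was 2.52 (SE 0.65). The term assumes 1 effect of that signal in both surgeries. Among FSAP-deficient arrays, those with the signal stood lower in sham (-1.15 against -0.58 and -0.81). After BDL they stood higher (3.02 and 1.75 against 0.89). The term therefore cannot decide how much of the difference lies with that signal. With slide as a block the difference was 3.26 (SE 1.30). Both genotypes of 1 surgery never shared a slide, so this value cannot decide whether slide is the cause. The calls of the single genes ended under both settings. A lower share of hepatocytes would raise markers of other cells alike, but MHC class II exceeded the mean of the neutrophil, B cell, erythroid and cholangiocyte lists by 2.66 (SE 0.57), and those lists stood at 0.21 (SE 0.17). That mean depends on the lists chosen. It leaves out the T and NK cell, stellate and macrophage lists, whose medians were also higher in FSAP-deficient livers after BDL, though by less than MHC class II. More or more active antigen-presenting cells without FSAP may account for the pattern, which was not tested. Part or all of the pattern may still lie with the Y-linked signal. Without the arrays that carry it, which leaves 1 FSAP-deficient array, the difference was 1.87.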

How the results depend on the processing

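Leaving out the 3 arrays with Y-linked signal, a term for them and fry were chosen after seeing the data; all other alternatives were fixed before. The cause of a change was not tested unless stated. Signal near background limits dim genes, such as Habp2 in FSAP-deficient livers, to bounds. Without the arrays with Y-linked signal FSAP-deficient livers after BDL have 1 array, assumed to vary like the other groups.

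Genes changed after BDL in WT numbered 4838 to 6130 when 1 array was left out and 3304 with slide as a block, and in FSAP-deficient livers 6217 to 6906 and 4190. The block leaves 1 array on one side of each, so its tests rest on fewer arrays. For genotype in sham, the main 3 became 2 to 3 without 1 array, 1 with only the groups compared, 168 with array weights, and 0 with the filter on all 12 arrays (limma), which removes Habp2 by construction. For genotype after BDL, the main 42 became 6 to 95 without 1 array, 135 with normexp, 67 with quantile normalization, 65 with median scaling, 97 with a trended robust variance, 11 with the replicate block, 6 without a filter, 6 with slide as a random and 2 as a fixed block, 3 with only the groups compared and 5 without the Y-linked arrays. For the average, the main 3 became 2 to 4 without 1 array, 6 with normexp and 1 with the filter on all 12. For the interaction, the main 2 became 0 to 22 without 1 array, 12 with normexp, 5 with the filter on all 12, 41 with array weights, 264 without the Y-linked arrays and 365 with a term for them, and 0 both without a filter and with the replicate block (limma, 2674 at an unadjusted p under 0.05 in the main setting).

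Replicate numbers did not pair the arrays: over 18 same-number pairs the correlation of deviations ran from -0.20 to 0.19 (median 0.012, other pairs -0.011), so the replicate block says nothing of weaker effects.

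Lists moved, in the order of the comparisons, in 25 to 27, 22 to 25, 10 to 16, 17 to 22, 12 to 23 and 18 to 26 cases without 1 array. With an estimated correlation they numbered 0, 1, 0, 0, 0 and 0, and with fry 24, 25, 0, 2, 0 and 1. In sham 11 moved without the Y-linked arrays, and in the average 13 with slide as a block. Habp2 stood at -12.18 to -10.53 in sham and -12.13 to -12.01 after BDL without 1 array, and at -11.08 in sham with only the groups compared, where it missed the threshold. The correlation of BDL effects was 0.772 to 0.827 without 1 array and 0.687 with slide as a block.

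These values changed sign, and no single gene among them passed in either setting. In sham, with slide as a block, Fn1 turned to 0.24, Timp1 to -1.12, Tgfb1 to 0.48, Krt19 to -0.12, Cyp7a1 to 0.24 and Cd74 to 0.29; in the average Acta2 turned to -0.30, Col1a1 to -0.79, Col1a2 to -0.95, Col3a1 to -0.65, Pdgfrb to -0.15 and Cyp7a1 to 0.36; and in WT the cell cycle median turned to -0.37 and the stellate median to -0.024. Cyp7a1 after BDL between genotypes turned to -0.011 with normexp, -0.087 with median scaling and -0.24 without the Y-linked arrays. Fn1 in FSAP-deficient livers turned to 0.35 with quantile normalization, 0.35 in the series matrix and 0.074 without the Y-linked arrays. In the average Acta2 turned to -0.041 with median scaling and -0.14 with array weights, and Cyp7a1 to 0.0095 with array weights and 0.10 with the term. Timp1 turned to -0.047 in the interaction with array weights. Without the Y-linked arrays Cyp7a1 turned to 0.10 in sham and -0.34 in the interaction, the interferon median in FSAP-deficient livers to -0.26 and the male-biased median after BDL to -0.18 (-0.70 with the term). In the interaction, with slide as a block, the female-biased median turned to -0.30 and the fatty acid oxidation median to -0.032. With the term Col1a2 and Col3a1 turned to 0.18 and 0.12 in sham.

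Without 1 array, Cyp7a1 ranged from -0.84 to 0.086 for BDL in FSAP-deficient livers, -0.87 to 0.10 in sham, -0.20 to 0.26 after BDL, -0.43 to 0.059 in the average and -0.088 to 0.88 in the interaction. Krt19 ranged from -0.026 to 0.38 in sham, -0.00788 to 0.87 after BDL and -0.17 to 0.71 in the interaction, Fn1 from -0.37 to 0.037 in FSAP-deficient livers, Acta2 from -0.23 to 0.30 and Tgfb1 from -0.076 to 0.25 in the average, and Timp1 from -0.45 to 1.69 in the interaction.

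For named genes over all alternatives, 2960 values kept direction and side of the threshold for BDL in WT, 162 were weaker and 2 stronger; in FSAP-deficient livers 2962 kept both, 179 were weaker and 5 reversed; and for genotype after BDL 689 kept both, 238 were weaker, 22 stronger and 8 reversed. In sham 404 kept both, 1 was stronger and 12 reversed, in the average 403 kept both, 16 were weaker, 1 stronger and 19 reversed, and in the interaction 604 kept both, 10 were weaker, 23 stronger and 8 reversed. For the lists that moved and are described in the report, which leaves out lists given only by their interaction median, the values that kept both numbered 467 of WT (17 weaker, 2 reversed), 409 of FSAP-deficient (22 weaker, 1 reversed), 86 in sham (4 weaker), 224 after BDL (8 weaker, 2 reversed), 70 in the average (2 weaker) and 191 in the interaction (1 weaker).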

Other observations

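The tests of the male-biased pattern below, the search for genes moving in opposite directions and the count of splits without Habp2 were chosen after the result was seen, while those of chromosome 19 and the other splits were fixed before it.

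Of the 4706 genes that changed after BDL in both genotypes, 35 went opposite ways, 17 of them lower in WT and higher in FSAP-deficient livers and 18 the reverse. In the first set Ccl5, a T cell chemokine, was at -2.15 in WT and 2.74 in FSAP-deficient livers, Gzmb, granzyme B of killer cells, at -2.58 and at least 3.02-fold higher (not well above background on any FSAP-deficient sham array), Gzma at -1.24 and 1.67, Cd3d, a chain of the T cell receptor complex, at -1.68 and 1.40, and Lck, its kinase, at -1.46 and 0.97. The T and NK cell list stood at 0.82, -0.38 and -0.33 on the FSAP-deficient BDL arrays and at -1.60, -0.02 and -0.51 on the FSAP-deficient sham arrays, so replicate 1 of each group, both with Y-linked signal, weighs on such rises. Interferon-induced Gbp4 stood at -2.05 and 2.18, and Nlrc5, an activator of MHC class I genes, at -0.85 and 0.71. In the reverse set Arg1, the arginase of the urea cycle, was at 0.61 and -0.56. None of the 35 passed the interaction test (adjusted p from 0.0727 to 0.139, limma), and these genes were picked for their opposite directions.

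Male-biased liver genes were higher in FSAP-deficient than in WT sham livers, by 1.499 (SE 0.789, under 2 SE) in the group mean of each array's list median. None of the 20 members passed, and the list moved neither with an estimated correlation (adjusted p = 0.588) nor with slide as a block (0.78). Without the array with Y-linked signal the difference was 0.47 (SE 0.20), so unequal Y-linked signal is a candidate explanation for most of it. That array also lay alone on its slide and scan day, and 0 other FSAP-deficient sham arrays carried Y-linked signal on another slide, so slide and scan day cannot be told apart from it. The labels do not give the sex of the mice, but Y-linked signal without Xist reads as male, so sex goes with that signal here. The genotype itself stays open.

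Genes near Habp2 could differ by genotype if DNA of the donor strain stayed around the targeted gene. Of 235 genes within 20 Mb on chromosome 19, 17 differed at an unadjusted p under 0.01 in the average over surgeries, or 7.23%, against 1.81% on other autosomes and 2.16% on the rest of chromosome 19. The 17 included Ablim1 at -0.39 (0.714 Mb from Habp2), Got1 at -1.08 (12.8 Mb) and Cyp2c23 at 2.14 (12.3 Mb). Only 2 of 100 splits gave as many, the highest other being 17, which is under the share of 0.05 fixed beforehand. The splits take no account of slides or of Y-linked signal, which differ between the genotypes. The sham and BDL differences had the same sign in 100 of the 235 genes. Among the 17, which were picked on the average of both, 14 did. Across all 235 genes the sham and BDL differences correlated at 0.106, above the median of -0.189 over 1385 windows elsewhere but reached by 5.49% of them, so donor DNA, or a regional effect of the deletion, stays open.

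For the other counts, 3 arrays against 3 make 10 splits, too few for a share under 0.05. For BDL in WT 6415 genes changed, and the highest other split gave 0, while 27 lists moved against 20. In FSAP-deficient livers the counts were 7624 against 11 genes and 24 against 27 lists, with 5 of 10 splits giving as many lists. Between genotypes in sham they were 17 against 14 lists and 3 against 1 genes. The 3 hold both Habp2 probes, which the genotype itself fixes, so that gene count decides nothing about chance. After BDL the counts were 42 genes, both probes included, against 5 and 20 against 23 lists, with 4 of 10 splits giving as many lists. In each of the others 1 of 10 splits, the real one, gave the count. For the average over surgeries 4 of 100 splits gave as many as 3 genes (highest other 8). As 2 of the 3 are these probes, this count decides nothing either. Without these probes 11 of 100 splits gave as many as the 1 gene left (highest other 8), so chance cannot be excluded for it, nor for the lists, where 31 of 100 gave as many as 20 (highest other 26).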
